A study of Mus musculus with 6 samples.

How the data were processed

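RNA-seq libraries from 6 cultures of mouse CD4+ T cells, 3 with DMSO and 3 with CX-4945, were analysed from the table the authors deposited. Total RNA was extracted with Trizol and libraries were made and sequenced on the Illumina platform by Genewiz, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The aligner, its version, the annotation release, the strand setting and the counting options are not given in the sources used here. Genes overlapping on opposite strands therefore cannot be told apart.

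The deposited table held 38924 gene rows. Its counts of unique exon reads were whole reads per gene placed at a single locus, not normalized, per the file headers. Its group means were the authors' RPKM, which the values show to be total exon reads, shared reads included, scaled by exon length and by a common total. Its comparison columns held the authors' t-test on log2 values of quantile-normalized RPKM, per the file headers and the values. Of 14649 genes with a corrected p-value in the authors' deposited table, 48 lay under 0.05, 24 higher and 24 lower in treatment. All 48 passed here with the same sign.

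Each column of the table names its group but carries no replicate number of the labels, so columns were used as replicates of their group without pairing. The design text calls the replicates biological but does not say whether each came from a separate mouse, so p-values measure the spread between these cultures. The unique exon reads were the only values per library used, and 84 other per-library value columns were not used. That choice was made after a first look at the table, in which the authors' test results for Il17a, Foxp3, Actb and Csnk2a1 had been seen. Gene starts in the table count from 0, and 1 was added. Of 37606 Ensembl identifiers shared with GENCODE M21, 29248 then had the same start and 29069 the same end.

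Depth ranged from 22178614 to 26148189 uniquely placed exon reads per library. A count of 3 reads, the limit that a count of 0 allows, equals 0.115 to 0.135 CPM, a bound that covers counting error only. Pairs of libraries of the same group differed by far more than sampling noise (chi-square over degrees of freedom 3.92 to 27.7), so no library was treated as a duplicate.

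Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 12502. Libraries were scaled by TMM, with factors of 0.971 to 1.02. The main test was the edgeR quasi-likelihood F test of treatment, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 8.55%. The standard error of a log2 fold change was taken as its size over the square root of F. Levels are CPM after TMM scaling, and fold changes are those of the fit. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

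The test was tried on simulated counts with the means and depths of these libraries and 200 changed genes. It recovered 24% of genes changed 1.25-fold, 70% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 12 false calls among 12302 unchanged genes. The simulated genes were independent, so that trial does not cover correlated gene lists. It changed 200 of 12502 genes, whereas 7741 passed in the data. The adjusted threshold was therefore stricter in the trial, and its recovery shares are not those of the real test.

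The groups, the tests, 45 gene lists and most alternatives were fixed before the data were examined. The lists cover helper T cell lineages, signalling, metabolism, stress, proliferation, RNA makeup and markers of other cell types. Of their 626 genes given by symbol, 4 matched no row of the table. The 40 lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera called 17 lists, 5 higher and 12 lower. With a correlation estimated from the data it called 0, and 7 lists had an unadjusted p under 0.05. That form also takes its p-values from the residual degrees of freedom of the 6 libraries, which makes them larger even where the correlation is low. Fry, also in limma, called 29 lists for one direction and 39 for change in either direction. The preset correlation is low for called lists such as DNA replication (estimate 0.81), but not for others such as Th17 core (0.0034). Each list called is reported with its gene counts and both camera p-values, and each other list tested with its counts and the first.

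Genes were named by a fixed rule. It took the 10 highest and 10 lowest fold changes among genes past the threshold whose groups did not overlap and whose higher mean was at least 5 CPM, leaving out predicted models and pseudogenes. It also took a set of CK2, Th17 and Treg genes whatever their result, up to 4 members past the threshold in each list by smallest adjusted p, and the most abundant member of each cell type list. The rule named 196 genes, of which 195 were tested; some of them are not reported here.

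Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other low-count filters, robust dispersion, a minimum fold of 1.5, rows summed per symbol, other set tests and each library left out in turn. The 30 gene lists and families used only in the closing observations were chosen after the data had been seen. A dose of 2 mM is printed as the label writes it, and its unit could not be checked.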

Results

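The study profiled RNA from mouse CD4+ T cells cultured with an inhibitor of protein kinase CK2 or with its solvent. Naive splenic CD4+ T cells of C57 BL/6 mice were stimulated through CD3 and CD28 for 72 h with IL-6, IL-23 and TGF-beta 1. This mixture drives differentiation into Th17 cells, helper T cells that secrete IL-17. CX-4945 (silmitasertib) competes with ATP at the catalytic subunits of CK2, a constitutively active serine/threonine kinase, and is also known to inhibit CLK kinases. The labels give its dose as 2 mM, a unit that could not be checked. The design text names 3 biological replicates per group, so 3 DMSO and 3 CX-4945 libraries were compared. Libraries are named by the numbers of the deposited table, which are 1, 3 and 5 for DMSO and 2, 4 and 6 for CX-4945. They held 24650050, 24150828 and 24279368 uniquely placed exon reads with DMSO, and 24239681, 22178614 and 26148189 with CX-4945.

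The comparison of CX-4945 with DMSO asks how CK2 inhibition alters the choice between Th17 and regulatory T (Treg) cell fates, as the series title frames it. Of 21 tested genes of the Th17 core list 17 fell with the inhibitor, among them the cytokine genes Il17a and Il17f, whereas Foxp3, the transcription factor that defines Treg cells, rose 9.91-fold. All 25 DNA replication and 24 mitosis genes tested rose, and all 20 glycolysis genes and 12 of 16 CD4 T cell identity genes fell. With an estimated correlation between genes, camera called 0 of 40 gene lists (smallest adjusted p = 0.16; 7 lists had an unadjusted p under 0.05). Of 12502 genes tested with edgeR, 3831 were higher and 3910 lower in CX-4945 at a Benjamini-Hochberg adjusted p under 0.05. The change was at least 2-fold for 528 of the higher and 1099 of the lower genes. Tested against a minimum fold of 1.5, 1863 genes passed, 661 higher and 1202 lower. The groups did not overlap for 8720 genes (69.7%), where chance gives 10%. The leading principal component carried 83.6% of the variance and separated the groups.

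Genes of the 3 CK2 subunits had fold changes of 0.982 to 1.10. Csnk2a1, a catalytic subunit (chromosome 2, 152226839 to 152281852, mm10), had 118 ± 11.6 CPM (uniquely placed reads scaled to library size) with DMSO and 124 ± 8.12 CPM with CX-4945 (SD, n = 3; edgeR adjusted p = 0.455). The other catalytic subunit, Csnk2a2, had 65.1 ± 2.43 and 63.9 ± 2.50 CPM (SD, n = 3; edgeR adjusted p = 0.705). Csnk2b, the regulatory subunit, had 137 and 151 CPM (log2 fold change 0.14 ± 0.05 SE, edgeR adjusted p = 0.0345). That call was lost when DMSO library 3 or 5, or CX-4945 library 2, 4 or 6, was left out (adjusted p 0.061 to 0.104). It was also lost when adjusted over the list alone, where 0 of the 3 subunits passed.

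Of the 21 tested genes of the Th17 core list, 17 fell, 1 rose and 3 did not pass. Il17a (chromosome 1, 20730905 to 20734496), which encodes the signature cytokine IL-17A, dropped from 127 ± 41.3 to 25.7 ± 6.18 CPM (SD, n = 3), 4.94-fold lower (log2 fold change −2.31 ± 0.27 SE, edgeR adjusted p = 0.000185). Il17f, its neighbour on the same chromosome (20777151 to 20784270), dropped from 1183 ± 291 to 417 ± 98.8 CPM (log2 fold change −1.50 ± 0.22 SE, edgeR adjusted p = 0.000563). Il23r (chromosome 6, 67422932 to 67491855), the receptor subunit for a cytokine present in the culture, fell 9.71-fold, from 20.3 ± 2.83 to 2.08 ± 0.37 CPM (edgeR adjusted p = 1.23e-05). Rora (chromosome 9, 68653786 to 69388246), a nuclear receptor gene of the Th17 lineage, fell 2.93-fold. Stat3, the transcription factor activated by IL-6 and IL-23, fell 1.54-fold, and its target Socs3 fell 1.70-fold. Ltb4r1 fell 3.86-fold, Hif1a 1.80-fold, Maf 1.23-fold and the cytokine gene Il21 1.35-fold. The riser was Tmem176b, with 8.05 and 11.4 CPM. The 3 genes that did not pass were Cd5l, Tmem176a and the chemokine gene Ccl20, which averaged 29.4 ± 15.6 and 29.6 ± 1.71 CPM; these 4 genes fell outside the rule for named genes and were chosen after their values were seen. Il22 held 24 reads over the DMSO libraries and 9 over the CX-4945 libraries, too few to be tested. Camera, which compares a list with all other genes, called the list lower (adjusted p = 1.99e-07; adjusted p = 0.16 with an estimated correlation).

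**Figure D1:**
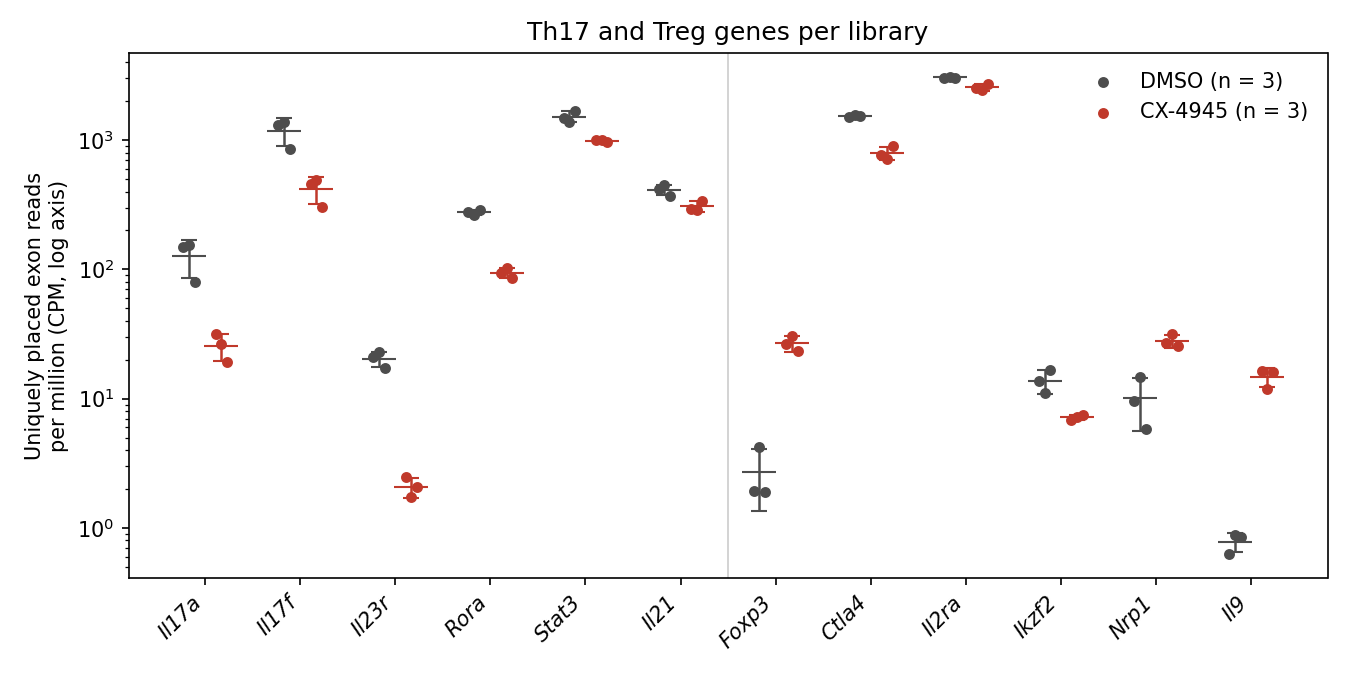
Uniquely placed exon reads in CPM (log axis) of 12 genes in 3 DMSO libraries (grey points) and 3 CX-4945 libraries (red points), with the mean and SD of each group as bars. Il17a averaged 127 CPM with DMSO and 25.7 CPM with CX-4945, and Foxp3 averaged 2.70 and 26.8 CPM; the groups do not overlap for any gene drawn.

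In the pathogenic Th17 signature, genes tied to inflammatory Th17 cells, 8 of 16 fell and 2 rose (camera adjusted p = 0.000327; adjusted p = 0.239 with an estimated correlation). Tgfb3 fell 11.4-fold, from 185 ± 53.5 to 16.2 ± 0.67 CPM, Stat4 fell 3.59-fold, Lrmp 2.27-fold and Gzmb 2.39-fold. Csf2, which encodes GM-CSF, rose 2.03-fold from 1.30 CPM. The non-pathogenic signature had 1 gene higher and 3 lower of 7 (camera adjusted p = 0.784). Its riser was Il9, a cytokine gene, which went from 0.78 ± 0.14 to 14.8 ± 2.50 CPM (SD, n = 3; log2 fold change 4.23 ± 0.20 SE, edgeR adjusted p = 1.13e-05). The list of JAK-STAT and STAT3 targets also holds pathway components, such as JAK, STAT and receptor genes, so it does not measure target output alone. In it 16 of 21 genes fell and 2 rose (camera adjusted p = 0.0077, or 0.378 with an estimated correlation). Jak2 fell 1.55-fold, Il2rb 1.42-fold and Stat5b 1.85-fold, while Socs2, a STAT5-induced feedback inhibitor, rose 2.46-fold.

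Foxp3 (chromosome X, 7579676 to 7595243) went from 2.70 ± 1.35 CPM with DMSO to 26.8 ± 3.70 CPM with CX-4945 (SD, n = 3; log2 fold change 3.31 ± 0.27 SE, edgeR adjusted p = 4.07e-05). In the authors' deposited table, its mean RPKM was 0.94 in control and 17.0 in treatment, a ratio of 18.04 that includes reads placed at several loci. Of the 24 tested genes of the Treg list, Foxp3 included, 8 rose and 12 fell, and camera did not call the list (adjusted p = 0.241). Fry asks whether the genes of a list move one way on balance, without comparing them with other genes. It called the Treg list lower (fry adjusted p = 0.00387). Because fry called 29 of the 40 lists in this way, that call does not set the Treg list apart. Ctla4, an inhibitory receptor gene, fell from 1532 ± 29.3 to 791 ± 94.0 CPM (edgeR adjusted p = 5.66e-05). Ikzf2, which encodes Helios, fell 1.92-fold, Tigit 4.39-fold, Swap70 3.17-fold and the cytokine gene Il10 1.45-fold. Il2ra, the IL-2 receptor alpha chain, fell 1.19-fold (edgeR adjusted p = 0.00857), a call lost without CX-4945 library 2 (adjusted p = 0.0556). Nrp1, a surface receptor carried by many Treg cells, rose from 10.0 ± 4.37 to 28.0 ± 3.29 CPM, and was also chosen after its values were seen.

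Genes of other helper lineages were mostly lower. In the Th1 list 9 of 14 fell and 1 rose (camera adjusted p = 0.00107; adjusted p = 0.239 with an estimated correlation), with Il12rb2 3.68-fold, Cxcr3 3.06-fold, Il12rb1 2.15-fold and Tbx21 1.55-fold lower. Ifng, the main Th1 cytokine gene, was low in both groups at 1.80 ± 0.83 and 1.86 ± 0.20 CPM (SD, n = 3; edgeR adjusted p = 0.912). In the Tfh list 8 of 11 fell (camera adjusted p = 0.0402; adjusted p = 0.308 with an estimated correlation), led by Ascl2, 5.60-fold lower. That list call was lost without DMSO library 3 or CX-4945 library 6 (camera adjusted p = 0.142 and 0.0671). Of 9 Th2 genes 5 fell and 2 rose (camera adjusted p = 0.584); Il4ra fell 1.53-fold and Areg rose 3.91-fold. Gata3, the Th2 regulator, fell 1.64-fold (edgeR adjusted p = 0.0193), a call lost without DMSO library 1, CX-4945 library 2 or CX-4945 library 4 (adjusted p = 0.0671, 0.0757 and 0.0694). Of the naive and quiescence genes, 10 of 16 fell and 2 rose (camera adjusted p = 0.00112; adjusted p = 0.258 with an estimated correlation). Il7r fell 3.42-fold, Cd27 3.20-fold, Satb1 2.94-fold and Btg1 1.91-fold. Of 11 immune checkpoint genes, 6 fell and 0 rose (camera adjusted p = 0.0143; adjusted p = 0.258 with an estimated correlation), among them Lag3, 2.11-fold lower, and Btla, 2.00-fold lower.

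Cell-division lists were higher with CX-4945. All 25 DNA replication genes rose, with a list median of 0.89 on the log2 scale (camera adjusted p = 1.53e-11; adjusted p = 0.378 with an estimated correlation). Mcm10 rose 2.17-fold, Cdt1 2.08-fold, Mcm7 2.05-fold and Rfc4 1.85-fold. All 24 mitosis genes rose, with a median of 0.95 (camera adjusted p = 1.35e-27; adjusted p = 0.258 with an estimated correlation). Ccnb2, a mitotic cyclin, went from 83.6 ± 4.26 to 181 ± 6.07 CPM, Kif11 rose 1.97-fold and Cenpf 1.87-fold. Of 20 ribosome biogenesis genes 19 rose (camera adjusted p = 8.80e-07; adjusted p = 0.378 with an estimated correlation), including Nop56, 1.80-fold, and Nop58, 1.77-fold. Among 35 histone genes taken by symbol, which include variant histones such as H2afx and H2afz, 14 rose and 3 fell (camera adjusted p = 0.0402; adjusted p = 0.2935 with an estimated correlation). H2afx rose 2.62-fold, while the summed level of the 35 genes was 2343 CPM with DMSO and 2127 CPM with CX-4945. The histone call was lost without DMSO library 3 (camera adjusted p = 0.112) and with a filter of 5 CPM in 3 libraries (camera adjusted p = 0.119). Myc, a growth-promoting transcription factor gene, fell 1.21-fold.

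All 20 glycolysis genes fell, with a median of −0.67 on the log2 scale (camera adjusted p = 2.52e-10; adjusted p = 0.308 with an estimated correlation). Aldoc, an aldolase, fell 8.54-fold from 266 ± 52.6 to 31.1 ± 6.67 CPM, Pdk1 fell 2.13-fold, Hk1 1.88-fold and the lactate exporter Slc16a3 1.70-fold. Of 21 cholesterol synthesis genes, 17 fell and 0 rose (camera adjusted p = 2.14e-05; adjusted p = 0.2935 with an estimated correlation). Hsd17b7 fell 2.15-fold, Lss 2.02-fold, Hmgcs1 1.77-fold and Sqle 1.45-fold. The fatty acid synthesis list was split, with 3 of 11 higher and 5 lower (camera adjusted p = 0.425); Scd1 fell 2.92-fold and Fasn rose 1.57-fold. In the ATF4 and amino acid response list, 17 of 24 genes rose and 2 fell (camera adjusted p = 0.0001445; adjusted p = 0.588 with an estimated correlation). The serine and one-carbon enzymes Shmt2 and Phgdh rose 2.07-fold and 2.05-fold, Aldh18a1 rose 1.75-fold and Mthfd2 1.60-fold.

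**Figure D2:**
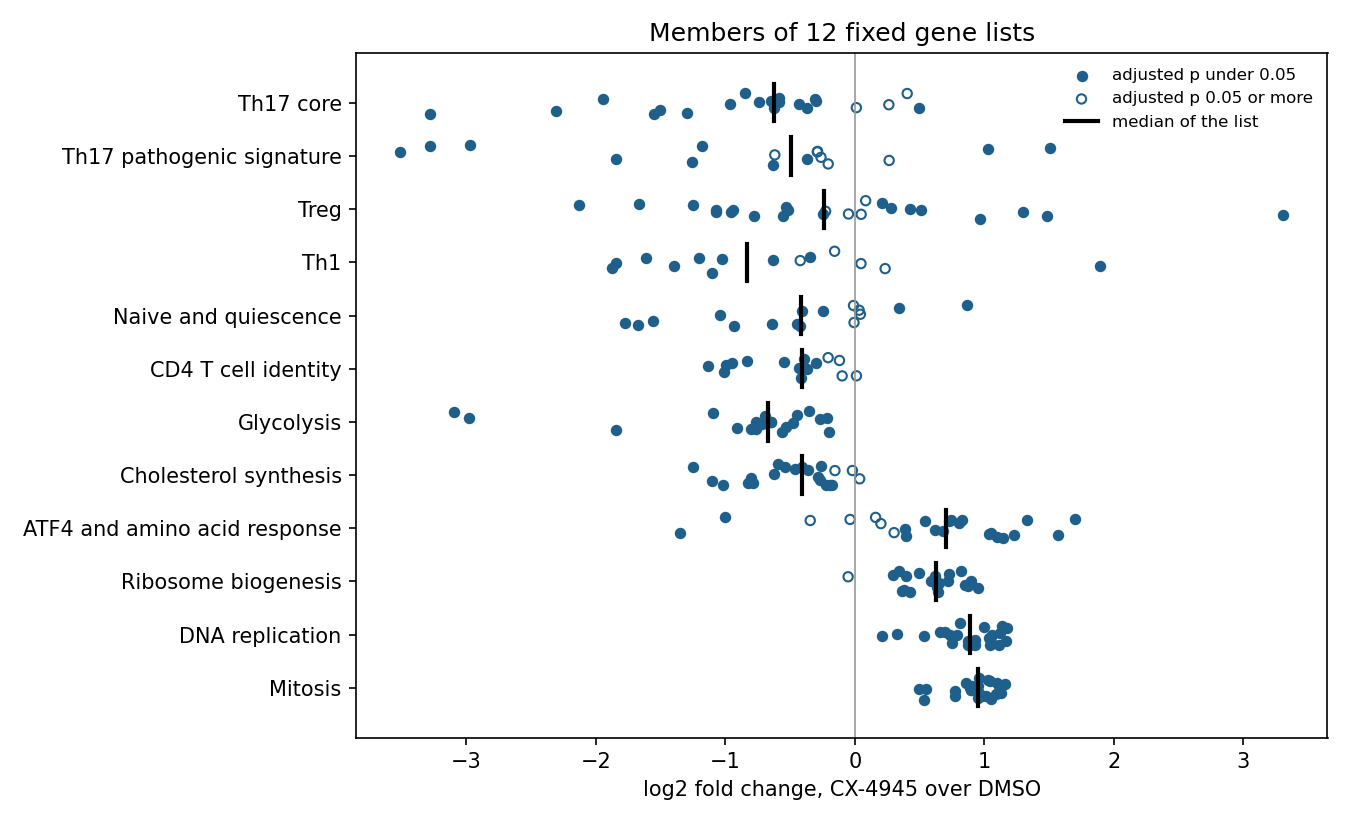
Log2 fold change of CX-4945 over DMSO for each tested member of 12 gene lists; filled points passed the adjusted p threshold of 0.05, open points did not, and black bars mark list medians. All 24 mitosis and 25 DNA replication genes lie above 0 and all 20 glycolysis genes below it, while the Treg list spreads to both sides with Foxp3 at 3.31.

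Several signalling and stress lists had genes past the threshold in both directions and were not called by camera. Over all genes tested 61.9% passed, 3831 higher and 3910 lower, so passing members in both directions do not by themselves mark a list. Of 18 genes of T cell receptor activation 7 rose and 5 fell (camera adjusted p = 0.719; list median 0.08 and mean −0.09 on the log2 scale), with Cd69 1.66-fold and Egr1 1.68-fold higher and Tnfrsf9 8.67-fold lower. Il2 had 2.39 ± 1.32 and 4.34 ± 1.27 CPM (SD, n = 3; edgeR adjusted p = 0.0886) and passed only when DMSO library 3 was left out, where its log2 fold change was 1.28. Of 19 TGF-beta signalling genes 7 rose and 7 fell (camera adjusted p = 0.497; list median 0.13, mean −0.0067 and camera direction lower), with Smad3 1.91-fold and Tgfbr2 1.47-fold lower. The NF-kB target list had 5 of 18 genes higher and 7 lower (camera adjusted p = 0.809), and the PI3K-AKT-mTOR list 7 of 20 higher and 8 lower (camera adjusted p = 0.815). Of 21 CLK and SR splicing factor genes 12 rose and 5 fell (camera adjusted p = 0.2); Srsf10 rose 1.38-fold, Tra2b 1.38-fold and Srsf4 1.26-fold, and the kinase Srpk2 fell 1.70-fold. Of 16 unfolded protein response genes 8 rose and 1 fell (camera adjusted p = 0.241). Heat shock genes split into 7 higher and 4 lower of 11 (camera adjusted p = 0.218), p53 targets into 9 higher and 6 lower of 20 (camera adjusted p = 0.584), and NRF2 targets into 4 higher and 5 lower of 14 (camera adjusted p = 0.975, direction higher, against a list median of −0.08 on the log2 scale). The apoptosis list had 2 genes higher and 3 lower of 14 (camera adjusted p = 0.755), with the pro-apoptotic Bcl2l11 2.94-fold lower. Of its higher genes Xiap lost its call without DMSO library 1 or CX-4945 library 2 or 4 (edgeR adjusted p 0.0558 to 0.0941). Of 17 lysosome and autophagy genes 12 fell and 3 rose. That list passed camera (adjusted p = 0.0453; adjusted p = 0.378 with an estimated correlation) and was lost without DMSO library 1 or 3 or CX-4945 library 2 or 6 (adjusted p = 0.0533, 0.0736, 0.0674 and 0.0851).

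Of 15 type I interferon response genes 9 rose and 2 fell, and camera did not call the list (adjusted p = 0.196). The list median, relative to each gene's mean over the libraries, was 0.51, −0.04 and 1.14 on the log2 scale in libraries 2, 4 and 6. Without CX-4945 library 4 the list passed at the preset correlation (camera adjusted p = 0.00133). Over all libraries its adjusted p was 0.842 with an estimated correlation. Oasl2 had 0.140 ± 0.0236 CPM with DMSO, close to what 3 reads are worth in a library (0.115 to 0.135 CPM), and 1.17 ± 0.675 CPM with CX-4945. Its log2 fold change went from 3.04 to 2.44 without CX-4945 library 6. Of 17 interferon gamma response genes 7 fell and 2 rose (camera adjusted p = 0.346), including Gbp2, 1.87-fold lower.

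**Figure D3:**
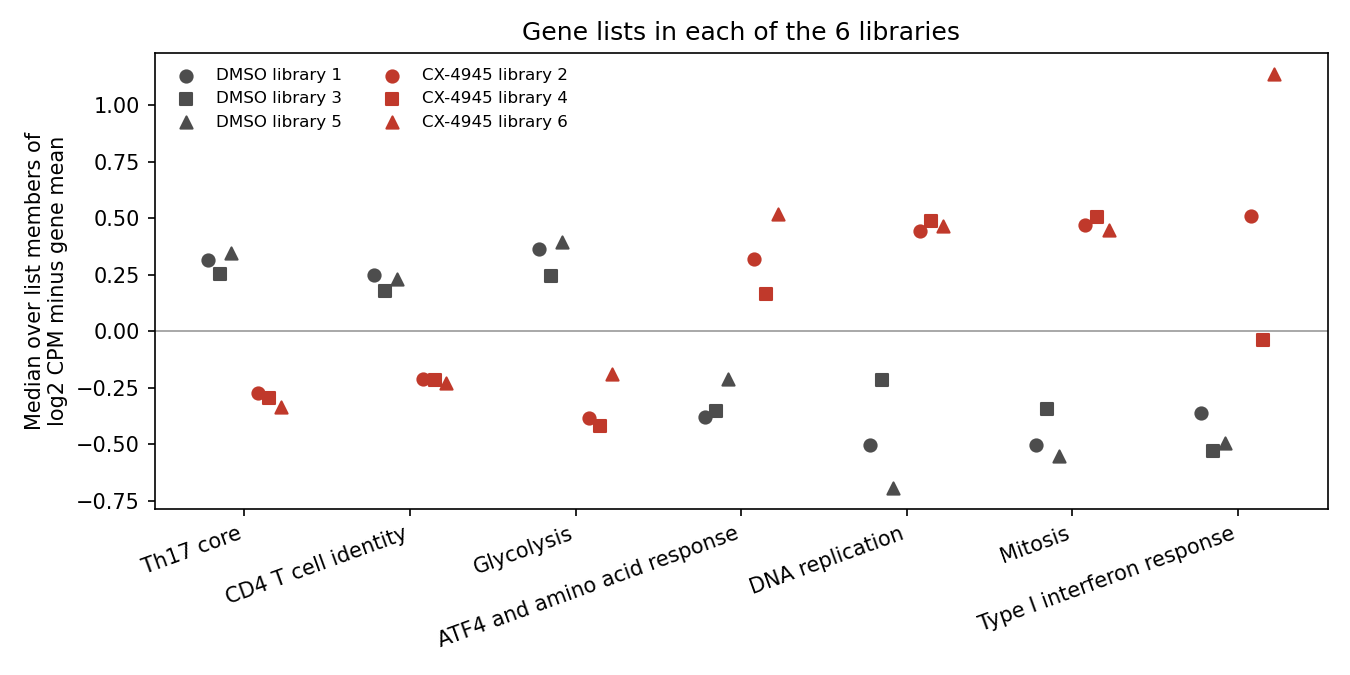
Median over list members of log2 CPM minus each gene's mean over the 6 libraries, for 7 gene lists; grey symbols are DMSO libraries 1, 3 and 5 and red symbols are CX-4945 libraries 2, 4 and 6. The type I interferon list runs from −0.04 in CX-4945 library 4 to 1.14 in library 6, and DNA replication runs from −0.70 in DMSO library 5 to −0.22 in library 3.

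The CD4 T cell identity list was lower, with 12 of 16 genes past the threshold and 0 higher (camera adjusted p = 7.95e-07; adjusted p = 0.258 with an estimated correlation). Cd3g fell 2.19-fold, Cd4 2.02-fold, Cd3d 1.99-fold and the costimulatory receptor Cd28 1.93-fold. Lck, the most abundant member, had 715 ± 17.7 and 668 ± 25.1 CPM (SD, n = 3; edgeR adjusted p = 0.137). Of 10 cytotoxic granule genes 6 fell and 2 rose (camera adjusted p = 0.0107; adjusted p = 0.378 with an estimated correlation), a call lost without DMSO library 3 (adjusted p = 0.0662). The B cell list summed to 70.8 CPM with DMSO and 53.8 CPM with CX-4945, and 4 of its 10 genes fell (camera adjusted p = 0.346). The macrophage list summed to 26.5 and 34.8 CPM, with 1 gene higher and 2 lower of 9 (camera adjusted p = 0.875, direction lower, with a list median of −0.26 and mean of −0.13 on the log2 scale). The higher gene, Cd68, lost its call without DMSO library 1 or 3 or CX-4945 library 2 or 6 (edgeR adjusted p 0.0622 to 0.139), and Mrc1, a lower gene, without DMSO library 1 or CX-4945 library 2 or 6 (edgeR adjusted p 0.0616 to 0.0794). NK cell genes summed to 10.06 and 11.01 CPM, with 2 higher and 1 lower of 5 (camera adjusted p = 0.777). Of the higher genes Klre1 lost its call without DMSO library 1, 3 or 5 or CX-4945 library 2 or 6 (edgeR adjusted p 0.0508 to 0.124). By edgeR, 0 of 5 gamma-delta and innate-like T cell genes passed (camera adjusted p = 0.815). The dendritic cell list summed to 285.5 and 115.2 CPM, and 3 of its 8 genes fell (camera adjusted p = 0.194), of which H2-Ab1, an MHC class II gene, went from 218 ± 35.9 to 61.3 ± 14.7 CPM. The neutrophil list had only 2 of its 10 genes tested, and these summed to 184.6 and 24.9 CPM. Nearly all of that was Ly6g, which fell from 181 ± 17.1 to 23.7 ± 0.88 CPM. The rest of the list lay below the expression filter, so this sum is not a measure of neutrophils. Cxcr2, the other tested gene of that list, had 3.10 and 1.26 CPM (edgeR adjusted p = 0.0228), a call lost without DMSO library 1 or 5 or CX-4945 library 2 or 4 (edgeR adjusted p = 0.0789, 0.0671, 0.0798 and 0.0795). The erythroid factor Klf1 had 1.34 and 0.676 CPM (edgeR adjusted p = 0.026), a call lost without DMSO library 1 or 5 or CX-4945 library 4 (edgeR adjusted p = 0.0695, 0.0666 and 0.0538). Of the CD8 pair, Cd8b1 fell 1.80-fold and Cd8a had 13.6 and 12.4 CPM. Of 10 stromal and endothelial genes 4 were tested, and they summed to 185.6 and 107.7 CPM. Among them Pecam1 fell 3.03-fold, Col1a1 fell 2.30-fold, and Pdpn had 78.4 and 71.6 CPM.

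The genes with the highest fold changes included several that DMSO cultures barely expressed. After Il9 came Tead1 (chromosome 7, 112679318 to 112906807), a transcription factor of the Hippo pathway, with 1.72 ± 0.505 and 29.4 ± 2.31 CPM (SD, n = 3; log2 fold change 4.09 ± 0.17 SE, edgeR adjusted p = 7.74e-06). Plk5 rose 11.4-fold and Thbs1, encoding thrombospondin 1, rose 9.91-fold. The log2 fold change of Thbs1 went from 3.31 to 4.43 without DMSO library 3. Pkhd1l1 rose 6.77-fold, Apol9b 6.52-fold, Olfm2 5.06-fold and Ifitm7 5.03-fold. Nav1 (the row numbered 1 of a symbol that the table lists more than once, hence uncertain) rose 6.48-fold. Without DMSO library 3 the log2 fold change of Apol9b was 3.30, against 2.71. The lowest fold change was that of Ptpn14 (chromosome 1, 189728268 to 189876695), a protein tyrosine phosphatase, which dropped from 42.9 ± 14.0 to 1.41 ± 0.20 CPM (SD, n = 3; log2 fold change −4.92 ± 0.29 SE, edgeR adjusted p = 1.67e-05). Cd93 fell 26.8-fold and Gipr, the receptor for an incretin hormone, fell 22.9-fold from 207 ± 82.4 CPM. Selenbp1 fell 18.5-fold, Etnk2 18.1-fold, Grin1 15.98-fold, Ltbp3 14.7-fold, Tifab 14.4-fold, Slamf7 12.3-fold and Rab33a 12.2-fold.

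Mitochondrially encoded genes took 1.57% to 1.92% of reads in the DMSO libraries and 1.67% to 2.23% in the CX-4945 libraries, with 4 of 12 genes higher and 1 lower (camera adjusted p = 0.425). The lower gene, mt-Co1, lost its call without DMSO library 1 or CX-4945 library 2 or 6 (edgeR adjusted p 0.0648 to 0.0925), and mt-Cytb, a higher gene, without DMSO library 1 or 5 or CX-4945 library 2 or 4 (edgeR adjusted p 0.0501 to 0.131). Of 76 cytosolic ribosomal protein genes 16 rose and 38 fell, with sums of 35600 CPM for DMSO and 30080 CPM for CX-4945 (camera adjusted p = 0.606). These have many near-identical pseudogene copies, so their uniquely placed reads are an uncertain measure. Counts adjusted over the list alone equalled those over all genes tested for all lists but 7; they gave 0 higher CK2 subunit genes, 6 lower fatty acid synthesis genes, 2 lower apoptosis genes, 4 higher lysosome genes, 13 lower CD4 identity genes, 0 higher macrophage genes and 2 higher mitochondrial genes.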

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

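Of the tests in this part, only the comparisons with the authors' RPKM and with their own test were chosen after results were seen. The count of 7741 genes was 7287 with DESeq2, 7712 with limma-voom and 6319 to 7993 with each library left out (3107 to 3954 higher, 3212 to 4039 lower). Among the settings run here, only the minimum fold of 1.5 moved it by over 1.5 times, to 1863 genes (661 higher, 1202 lower). That test excludes small changes by construction. Scaling by total count alone raised the higher share from 49.5% to 56.5% and shifted the median gene by 0.063 on the log2 scale. No gene called in the main test was called in the opposite direction under any of these settings. Of 186 named genes past the threshold, 0 reversed, 11 were lost without some library, 2 under another test or filter and 69 under the minimum fold. Where leaving out a library lost a call, the fold change itself moved little, by a factor of 1 (Csnk2b) to 1.22 (Klf1 without CX-4945 library 4). The reversals were of genes that had not passed: the log2 fold change of Csnk2a2 was 0.037 with total count alone, and with each library left out it ranged from −0.057 to 0.00505 for Csnk2a2, −0.277 to 0.358 for Ifng, −0.366 to 0.064 for Cd8a and −0.225 to 0.014 for Pdpn. The cause was not tested. The authors' mean RPKM ratio correlated with the fitted change at Pearson r = 0.996 across 12501 genes, which are not independent replicates. It lay on the other side of 1 for 13 called genes. The authors' own test, made on other values, put far fewer genes under 0.05 after correction, 48 of 14649. Without correction, 6617 genes lay under 0.05 in the authors' test and 8273 in the edgeR test.

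The gene list calls depended on the set test. Camera called 17 lists, and 0 with an estimated correlation (smallest adjusted p = 0.16, for Th17 core). For Th17 core, the pathogenic signature, Th1, immune checkpoints and histones the estimates were 0.0034, 0.0057, −0.0026, −0.046 and 0.0056. These lie under the preset 0.01, so a higher correlation between genes cannot be why these lists were lost. The other lists lost had estimates of 0.024 (Tfh) to 0.81 (DNA replication). With an estimated correlation, camera also takes its p-value from the residual degrees of freedom of the 6 libraries, not from the number of genes. That raises p-values whatever the correlation. For the lists with higher estimates, its part was not told apart from that of correlation. Fry called 29 and its mixed form 39. The Treg list, not called by camera, had an adjusted p of 0.00387 with fry and 0.000798 with mixed fry. With each library left out camera called 13 to 18 lists, Th17 core kept an adjusted p of 3.34e-09 to 3.72e-06, and Treg 0.0851 to 0.4715. The 3 libraries per group make 10 splits, too few for a share under 0.05. The real split called 7741 genes and the highest other split 0. Every other split mixes DMSO and CX-4945 libraries on each side, so the treatment difference widens the spread within a side. Few gene calls there were thus fixed in advance, and list calls there still carry part of the treatment difference. For lists at the preset correlation the real split called 17 and the highest other split 19. At least as many lists as in the real split came from 3 of the 10 splits, the real one included, and at least as many genes from 1 of the 10. No paired analysis was possible by label, because the columns of the table carry no replicate numbers of the labels. For that reason the planned replicate block was not run. A block guessed from adjacent column numbers, which no label ties together, could have been fitted as an alternative but was not. No call was therefore checked under pairing. No pseudocount was varied, since counts were tested. In the simulation, made with the depth and number of these libraries, 24% of 1.25-fold changes were recovered. The parts of depth, of spread between cultures and of the small share of changed genes in that limit were not told apart.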

Other observations

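The lists and families in these first 2 paragraphs were chosen after the data were seen, and 30 were tested. Genes of the hypoxia response, known targets of HIF1, fell in 25 of 27 cases and rose in 0 (camera adjusted p = 2.84e-12; adjusted p = 0.223 with an estimated correlation). Adm went from 37.5 ± 11.4 to 3.59 ± 0.85 CPM (SD, n = 3), Ndrg1 fell 3.82-fold, Hilpda 2.67-fold and Bnip3 2.53-fold. Of 13 chemokine receptor genes 12 fell and 1 rose (camera adjusted p = 2.48e-06; adjusted p = 0.117 with an estimated correlation). Cxcr4 went from 251 to 110 CPM, whereas Ccr8 rose 1.73-fold. Of 30 interleukin receptor genes 20 fell and 2 rose (camera adjusted p = 2.56e-06; adjusted p = 0.117 with an estimated correlation). All 8 Gimap genes, lymphocyte GTPases, fell (camera adjusted p = 5.39e-06; adjusted p = 0.223 with an estimated correlation), and 7 of 9 Ly6 family genes fell (camera adjusted p = 1.40e-07; adjusted p = 0.117 with an estimated correlation). Ly6c1 went from 141 to 26.4 CPM and Ly6a from 637 to 210 CPM.

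Of 38 proteasome subunit genes 27 rose and 1 fell (camera adjusted p = 9.73e-05; adjusted p = 0.442 with an estimated correlation). Of 20 nucleoporin genes 15 rose and 1 fell (camera adjusted p = 8.29e-05; adjusted p = 0.287 with an estimated correlation), with Nup85 at 76.8 and 157 CPM. Kinesins, motor proteins of which many act in mitosis, had 20 of 33 genes higher and 6 lower (camera adjusted p = 4.96e-06; adjusted p = 0.117 with an estimated correlation). Solute carriers split evenly, 63 higher and 64 lower of 208 (camera adjusted p = 0.969). Camera called 17 of the 30 and 0 with an estimated correlation. The interleukin family is not among the 17 (camera adjusted p = 0.506); a first symbol pattern for it had also taken in receptor genes and passed, and it was corrected after that result was seen.

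All tests in the next 3 paragraphs were chosen after the patterns were seen. The first pattern is that cell-division lists rose while glycolysis and hypoxia-response lists fell. Scaling between libraries is argued against for the lists moving apart, since it shifts all genes of a library alike. No other scaling moved the median gene by more than 0.063 on the log2 scale. List medians were 0.89 for DNA replication, 0.95 for mitosis, −0.67 for glycolysis and −0.88 for hypoxia without Adm, a gene left out of this pattern. All scalings tried set libraries to a common total or a common typical gene. They cannot show a change in RNA per cell, so such a change stays open for the rise alone or the fall alone. A culture difference that also separates the DMSO libraries stays open. The difference between DMSO libraries 3 and 5 went in the treatment direction for 86.3% of the list members, and correlated with the treatment difference taken from the other libraries at r = 0.517 across 12502 genes, which are not independent replicates (the other 2 pairs of DMSO libraries gave 0.477 and 0.212). Libraries 3 and 5 were picked as nearest to and farthest from the CX-4945 libraries, and that choice by itself makes their difference run toward CX-4945, so these values decide nothing.

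The second pattern is the fall of the Th17 core list, for which the same explanation stays open. Between DMSO libraries 3 and 5, 13 of its 21 genes differed in the treatment direction, and the list median relative to each gene's mean was 0.25 in library 3 and 0.34 in library 5. The mean difference of the 21 genes, library 3 minus 5, was 0.175, opposite to the treatment (95% bootstrap interval over genes −0.024 to 0.408). The slope over all genes gives −0.234, which lies below that interval and so met the rule set for excluding the explanation. It is left open all the same, because the pair of libraries was picked as above, median and mean differ in sign, and the interval does not cover variation between cultures.

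The third pattern is that Foxp3 rose 9.91-fold while other Treg genes went both ways. Foxp3 was counted from uniquely placed reads only. With reads placed at several loci included, the authors' mean RPKM ratio was 18.04, so the size of the rise depends on which reads are counted. Treg cells carried over from the spleen cannot be told apart from induction of Foxp3. How many such cells remained after isolation of naive cells was not measured. The most abundant Treg list genes, such as Il2ra (3048 and 2564 CPM), are also expressed by activated T cells. The 9 other Treg genes under 40 CPM in DMSO had a median log2 fold change of −0.227 (95% bootstrap interval −0.942 to 0.969), with 2 called higher and 4 lower. A first form of the rule excluded carry-over when the upper bound was under 1, which 0.969 met; the rule was altered after that value was seen, because members that go both ways decide nothing, and the limit of 40 CPM was also picked knowing the levels.

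Libraries of different groups also varied together. Across genes, deviations from the group mean correlated at r = 0.394 between DMSO library 5 and CX-4945 library 6, at 0.318 between libraries 3 and 4, and at 0.0921 between libraries 1 and 2. The remaining 6 combinations ran from −0.379 to 0.102. No block was fitted from these combinations, so whether pairing would change any call was not tested.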
